A study of Caenorhabditis elegans with 12 samples.

How the data were processed

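Single oocytes were taken from the gonads of adult wild-type Caenorhabditis elegans, per the labels, at the positions called -1, -3 and -5. Positions are counted back from the spermatheca, so the -1 oocyte is the most proximal and the oldest of the 3. Each of the 12 libraries held the RNA of 1 oocyte, per the file headers, and each position had 4 libraries. Oocytes were lysed fresh and frozen, and libraries were made with the SMART-seq 3' DE kit, per the labels' protocols. This kit reads the 3' ends of polyadenylated transcripts after PCR and gives no count of molecules, so the intervals and floors below cover counting error only. Levels of the histone genes, like those of all genes, therefore concern polyadenylated transcripts and not all transcripts of a gene.

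The deposited count table holds whole reads per gene, which were not normalized by the authors. Reads were trimmed with cutadapt 1.18, checked with FastQC 0.11.5, aligned with STAR and counted with featureCounts, per the submitters' processing notes. The notes give featureCounts 1.5.3 and the file header gives 1.6.4. The counting command in the header named the WormBase WS271 annotation and carried no option for strand, for multi-mapping reads or for reads shared by overlapping genes. Strand therefore cannot tell reads of a gene from antisense reads, and reads in exons shared by overlapping genes could be lost. Near-identical genes could lose or share reads, which leaves the vitellogenins, histones, collagens, major sperm protein genes and the pair puf-3 and puf-11 uncertain. The genome build is not given in the sources used here, and coordinates are those of the count table. The authors also deposited 3 tables of pairwise DESeq2 comparisons (DESeq2 1.32.0, per the submitters' processing notes). Those tables give a mean signal, a log2 fold change with its error, a Wald score and a p-value per gene as the authors computed them. Only their log2 fold changes and the signs of their Wald scores were used here.

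The table held 46903 genes, none of its rows named anything other than a gene, and the identifiers of 44018 had a symbol in the reference annotation. Of the 46818 genes in both annotations, 46818 lay on the same chromosome and 69.1% had the same start and end. Genes were kept when edgeR 4.0.16 (R 4.3.3) judged their counts high enough for the design by position with its default filter, which left 8718. Library sizes were scaled with TMM factors. The level of a gene at a position was the summed count of its 4 oocytes over their summed scaled library sizes, in CPM (counts scaled to the library size), with an exact Poisson interval at 95%. A log2 ratio compared 2 such levels, and a sum under 3 counts over the group was set to that floor. The share of a list in the summed counts has an exact binomial interval. Leaving out each oocyte in turn was planned before the data were examined, and was applied to the ratios and medians that replaced the tests. Where leaving out 1 oocyte moved a printed ratio by over 1.5 times, the value without the oocyte of largest effect stands in the same paragraph.

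The results rest on no test between positions. The labels name no animals and each library is 1 cell, so a position was treated as 1 sample and has no replicate of its own. The plan fixed before the data were examined treated the oocytes of a position as replicates and tested them with edgeR. Those tests had been run and seen when the plan was set aside, because the file headers showed that each library was 1 oocyte. The planned edgeR test called no gene between any pair of positions or for a trend over the positions at an adjusted p-value under 0.05, and called some for the difference between the steps. DESeq2 1.42.0, run as an alternative on the counts, called some in each pair. These outcomes take oocytes as replicates, so no count from them is reported and no ratio named below rests on a call. A gonad arm holds 1 oocyte at each position and an animal has 2 arms, so the 4 oocytes of a position came from at least 2 animals, which the labels do not tell apart. The comparison of levels, the percentiles and the form of the naming rule given below were chosen after seeing the data. A trend over the positions and a difference between the steps were part of that plan and were left out with the tests.

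Gene lists were fixed before the data were examined. They cover tissues that could pass RNA or protein to the oocyte, cells that touch it, and groups of genes that work in the oocyte itself. Of the 21 lists, 20 had at least 3 measured members. For each list and comparison the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the percentiles 2.5 and 97.5 of those lists was described as standing apart. The random lists treat genes as independent, so a percentile describes these libraries and is not a test. In 60 such comparisons 3 would stand apart by chance if genes were independent. Each oocyte also had a score per list, the median over members of log2 (CPM + 1) minus the gene's mean over all oocytes. On simulated counts for oocyte -1 against oocyte -5 over 8718 genes, 4 of 60 unchanged lists lay outside the edges, and the median log2 ratio of a changed list was recovered within 0.26. Each gene was drawn independently there, so lists whose members vary together and oocytes that stand apart were not simulated. The percentiles are not calibrated for such lists, and the error of 0.26 is larger than several medians described below.

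Genes were named by rule. The first part took genes with a mean of at least 20 CPM over the oocytes of the 2 positions compared whose 4 oocytes of one position all lay above the 4 of the other, which happens by chance to 2.86% of genes. Of these, the 8 with the largest ratio each way were named for -1 against -5 and 5 each way for the other comparisons. The rule had first asked for an adjusted p-value as well, and that part was dropped with the tests. Further named genes were a fixed set of oocyte genes, up to 4 members with the largest absolute log2 ratio in each list described, and the 10 most abundant genes. No library was a copy of another of its position, since the smallest chi-square per degree of freedom between these was 44.2, and libraries of different positions were not compared in this way. Alternatives were RLE and upper-quartile factors, library totals, no filter, a filter of 10 counts in 8 libraries, mitochondrial genes left out of the library size, equal weight per oocyte, an adjustment for exonic length by a lowess line with a span of 0.3, and leaving out oocytes. Calculations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.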

Results

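RNA was sequenced from 12 single oocytes of adult wild-type gonads, 4 each at positions -1, -3 and -5. The series asks whether oocytes arrested in meiosis I acquire transcripts from somatic tissue, and how expression differs with the age of the oocyte. Libraries held 8358019 to 20446599 counts. The totals were 17540558, 11581919, 8358019 and 19104635 for replicates 1 to 4 of oocyte -1. For oocyte -3 they were 19430838, 11478753, 16140400 and 20446599, and for oocyte -5 11625118, 13634901, 11226569 and 15832936. On average 9747 ± 329 genes (SD, n = 4 oocytes) were detected at -1, 9007 ± 571 at -3 and 9690 ± 222 at -5. A count of 3 in 1 library corresponded to 0.147 CPM in the deepest library and 0.359 CPM in the shallowest. The floor used for ratios was 3 counts over the summed libraries of a position, which is lower in CPM. With each library a single cell and no animals named, the positions were taken as 1 sample each and no test of a difference is reported. Ratios below describe these 12 oocytes, and intervals on levels are exact Poisson intervals at 95% that cover counting error only.

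The 10 genes with the highest mean level over the 12 oocytes were led by the C-type lectin gene clec-87, at 21907 CPM in oocyte -1, 37974 in oocyte -3 and 25236 in oocyte -5, and by ndk-1, a nucleoside diphosphate kinase gene, at 20615, 31827 and 20988 CPM. F23A7.8, F23A7.4, the small heat shock protein gene sip-1, the ADP/ATP carrier gene ant-1.1, rmd-1, rpl-12, the elongation factor gene eef-1A.1 and clec-88 completed the 10. Replicates 1 and 3 of position -3 stood apart from the remaining libraries. Replicate 1 lay at 119.4 on the first principal component and replicate 3 at -114 on the second, and the components held 25% and 16% of the variance. After thinning to 8358019 counts these oocytes had 8453 and 8033 genes detected, against at least 9040 in each of the other 10.

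**Figure D1:**
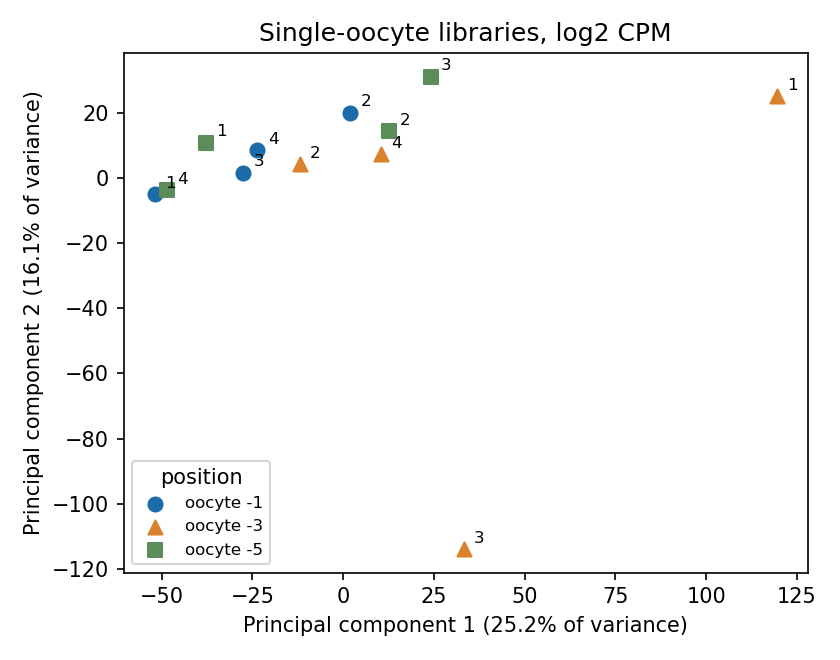
Positions of the 12 libraries on the first 2 principal components of log2 CPM, with axis labels giving the percent of variance and point labels the replicate number. Replicates 1 and 3 of oocyte -3 lie far from the other 10 libraries, which overlap between positions.

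Oocyte -1 against oocyte -5 compared the oldest oocyte with the youngest one sampled. Among genes with a mean of at least 20 CPM whose -1 oocytes all lay above the -5 oocytes, 5 had the largest ratios. Some genes outside these limits had larger ratios. ZC373.2 stood at 53.2 CPM (interval 51.4 to 55.0) in oocyte -1 and 1.96 CPM (1.6 to 2.4) in oocyte -5, a log2 ratio of 4.76. The gene ule-5, of the uterine lumen expressed class, stood at 46.1 CPM (44.4 to 47.8) against 2.07 (1.7 to 2.5), a log2 ratio of 4.47. F57C2.4, ZK813.3 and Y62H9A.5 had log2 ratios of 4.19, 3.64 and 3.57. Single -5 oocytes held most counts of several of these at that position. The ratio of F57C2.4 was 7.10 without replicate 1 of oocyte -5, that of ZC373.2 5.37 without its replicate 2, and those of ZK813.3 and Y62H9A.5 4.98 and 5.34 without its replicate 3. All 5 are protein-coding, and 4 of them lie on chromosome X. Y62H9A.5 (WBGene00013393) at X, 11882144 to 11882917, and ule-5 (WBGene00013394) at X, 11883127 to 11884043, are neighbours. ZC373.2 (WBGene00013867) lies at X, 10057925 to 10058437, ZK813.3 (WBGene00022822) at X, 3441839 to 3442458, and F57C2.4 (WBGene00010196) at II, 14525312 to 14526031. Smaller ratios were seen for H05C05.1 (1.31), the E2F-like gene efl-3 (1.27) and snf-1, a gene of the sodium-dependent transporter family (1.11).

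Among genes of at least 20 CPM whose -1 oocytes all lay below the -5 oocytes, the lowest ratio was that of K04C1.5, at 56.7 CPM (54.9 to 58.7) in oocyte -1 and 356 CPM (351 to 361) in oocyte -5, a log2 ratio of -2.65, or -3.24 without replicate 3 of oocyte -1. The hexosamine pathway gene gfat-2 stood at 421 against 1992 CPM (-2.24). Y75B12B.1 (-2.35), the mitochondrial processing peptidase gene mppa-1 (-2.04) and the lipid droplet protein gene ldp-1 (-1.82) were also lower in each -1 oocyte than in each -5 oocyte. So were 3 collagen genes, col-101 (-2.58), col-184 (-2.30) and col-119 (-2.12). In oocyte -5 replicate 4 col-101 reached 181 CPM, and without that oocyte the ratios of col-101, col-184 and col-119 were -1.02, -1.00 and -1.17.

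**Figure D2:**
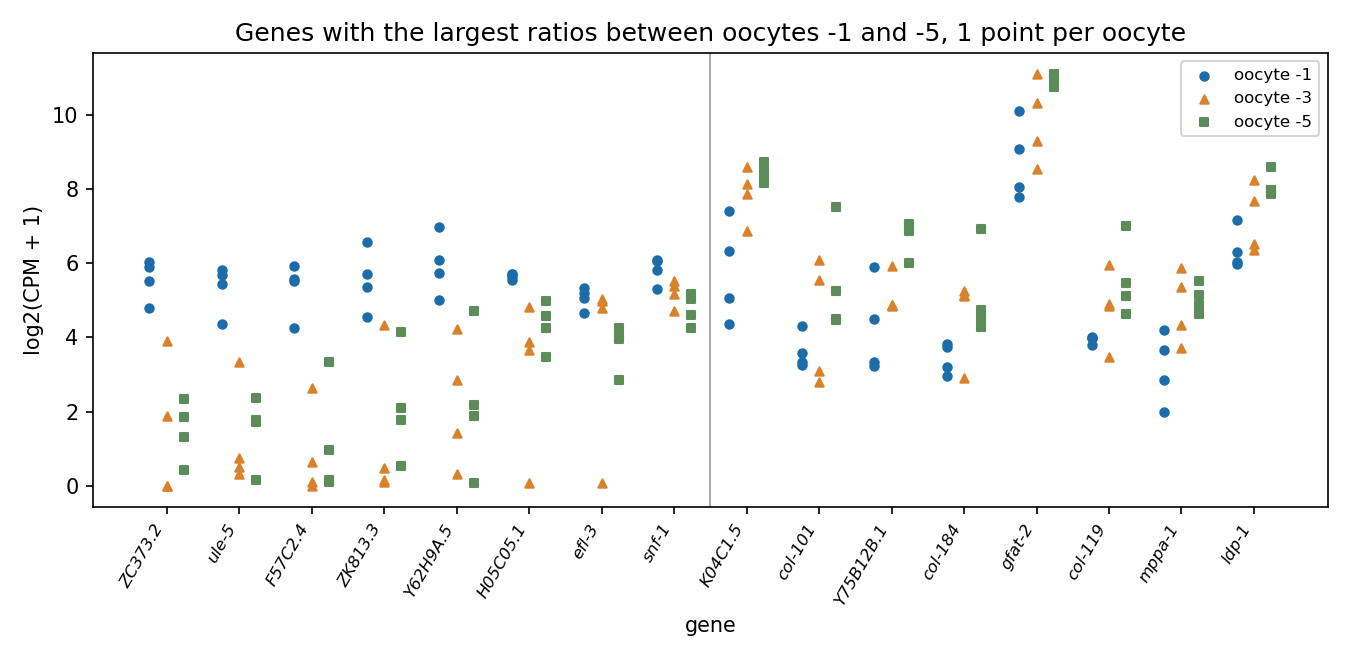
Level of each gene named for oocyte -1 against oocyte -5 by the size of its ratio, as log2 (CPM + 1), with 1 point per oocyte and 4 oocytes per position. Genes left of the line were higher in every -1 oocyte than in every -5 oocyte, as for ZC373.2 with 53.2 against 1.96 CPM, and genes right of the line were lower, as for K04C1.5 with 56.7 against 356 CPM.

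Among genes that act in the oocyte, the yolk receptor gene rme-2 stood at 1163 CPM (1154 to 1171) in oocyte -1, 1915 CPM (1904 to 1926) in oocyte -3 and 2624 CPM (2610 to 2638) in oocyte -5. Single oocytes ranged from 1023 to 1454 CPM at -1, 483 to 3241 CPM at -3 and 1914 to 3404 CPM at -5. The list of eggshell, yolk uptake and egg activation genes had a median log2 ratio of -0.24 between -1 and -5, with 9 of 33 members higher and 24 lower, at percentile 0.04 of the random lists. The permeability barrier genes perm-1, perm-2 and perm-4 had log2 ratios of -1.19, -2.56 and -1.47, and the fatty acid synthase gene fasn-1 -1.91. Oocyte -5 replicate 4 held much of the -5 level, with 1011 CPM of perm-2 and 1020 CPM of perm-4 against at most 220.1 and 311 CPM in the other -5 oocytes. Without it the ratios of perm-2, perm-4 and fasn-1 were -0.94, -0.05 and -1.24, and without oocyte -1 replicate 1 those of perm-2 and perm-4 were -3.43 and -2.58. Gonadal sheath and spermatheca markers took 0.170% of the counts of oocyte -5 replicate 4, against 0.0582% to 0.0813% in the other -5 oocytes. They took 0.0963% in oocyte -1 replicate 1, against 0.0632% to 0.0734% in the other -1 oocytes. Whether RNA of other cells set the perm-2 and perm-4 levels was not tested. The chitin synthase gene chs-1 stood at -0.84, the chitin-binding eggshell gene cbd-1 at -0.69 and egg-1 at -0.33. The Pumilio-family genes puf-3 and puf-11 stood at 322 and 350 CPM in oocyte -1 against 1020 and 1017 in oocyte -5, and lin-41, a regulator of oocyte growth and maturation, at 85.7 against 160 CPM. Other RNA-binding regulators lay closer to 0, with log2 ratios of -0.01 for oma-1, -0.19 for oma-2, -0.24 for puf-5, 0.15 for pos-1, 0.39 for mex-3, 0.07 for gld-1 and -0.50 for rnp-8. The 43 genes of that list had a median of 0.07 (percentile 98.4), 23 higher and 20 lower, and a mean of the opposite sign, -0.04. Without replicate 1 of oocyte -1 the median was -0.02.

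Ribosomal protein genes were higher in oocyte -1 than in oocyte -5 for 77 of 80 members, with a median log2 ratio of 0.45 (percentile 100). Examples were rpl-38 (0.97), rpl-26 (0.96), rpl-9 (0.77) and rps-22 (0.75). Against the list, rpl-12, among the 10 most abundant genes, stood at -0.19, or 0.08 without replicate 1 of oocyte -1. Leaving out 1 oocyte at a time gave medians from 0.148, without replicate 4 of oocyte -5, to 0.688, without replicate 4 of oocyte -1. Mitochondrially encoded genes were lower for 10 of 12 members, with a median of -0.40 (percentile 0), as for nduo-2 (-0.94), nduo-5 (-0.76), nduo-1 (-0.71) and ctb-1 (-0.71). Histone genes had a median of -0.25 (percentile 0.5), with 9 of 38 members higher, or 18 without replicate 1 of oocyte -1. In each comparison the histone ratios cover polyadenylated transcripts only. The linker histone gene hil-1 had no count in any -1 oocyte and was at least 14.8-fold lower than in oocyte -5, against the floor of 3 counts over the group. Leaving out 1 oocyte at a time, the histone median ranged from -0.470, without replicate 4 of oocyte -5, to -0.0667, without its replicate 2. Among other members hil-3 stood at -2.19, his-69 at 2.13 and his-1 at 1.61. These were genes of few counts, and the ratio of hil-3 was -4.49 without replicate 2 of oocyte -1, that of his-69 -0.19 without replicate 4 of oocyte -1 and that of hil-1 -3.17 at the floor without replicate 2 of oocyte -5. Proteasome genes had a median of 0.11 (percentile 99.9), 24 of 33 higher, as for rpn-13 (0.42), pbs-6 (0.42), rpn-2 (0.36) and rpn-8 (0.32), and rpn-13 stood at 1.02 without replicate 4 of oocyte -5. Cell cycle and spindle genes had a median of 0.07 (percentile 98.4), 35 of 58 higher, with gpr-2 at 0.71, bub-1 at 0.58, cyclin E gene cye-1 at -1.04 and wee-1.3 at -0.50. The cell cycle kinase gene cdk-1 stood at 0.10 and the cyclin B gene cyb-1 at 0.36.

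Markers of somatic tissues bear on the question of transcripts from the soma. Yolk protein genes, which are transcribed in the intestine, took 0.0150% of the counts at -1 (exact binomial interval 0.0146% to 0.0153%), 0.0104% at -3 (0.0102% to 0.0107%) and 0.0154% at -5 (0.0150% to 0.0157%). Those intervals cover counting error, and single oocytes ranged from 0.00493% to 0.0297% at -1, 0.00668% to 0.0124% at -3 and 0.00933% to 0.0261% at -5. Oocyte -1 replicate 4 was the highest, and without it the share at -1 was 0.00744%, below the share at -3, so the order of -1 and -3 turned on 1 oocyte. Their median log2 ratio between -1 and -5 was -0.22, at percentile 11.2. Single genes stood at -0.12 for vit-1, -0.38 for vit-2, -0.32 for vit-3, -0.87 for vit-4, 0.15 for vit-5 and 0.36 for vit-6. Leaving out oocyte -1 replicate 4 gave a median of -1.12 and ratios of -0.88, -1.27, -1.02, -1.94, -1.22 and -0.80 for vit-1 to vit-6, and vit-4 stood at 0.22 without oocyte -5 replicate 2. Intestine markers had a median of -0.19 (percentile 34.8) and took 0.00329% of the counts at -1, 0.00312% at -3 and 0.00337% at -5. Their shares in single oocytes ran from 0.00137% to 0.00606% at -1 and from 0.00169% to 0.00528% at -5. The share at -1 was 0.00187% and the median -1.27 without oocyte -1 replicate 4, and the median was 0.50 without oocyte -5 replicate 3.

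Hypodermis and cuticle markers were lower in oocyte -1 for 12 of 12 measured members, with a median of -1.01 (percentile 0). The lowest were grd-3 (-2.41), col-119 (-2.12), col-19 (-1.74) and col-140 (-1.68). That list took 0.178% of the counts of oocyte -5 replicate 4 and at most 0.0469% of the other -5 oocytes. Leaving that oocyte out gave a median of -0.45, and ratios of -1.17 for col-119, -0.63 for col-19 and -0.83 for col-140. Muscle markers had a median of 0.41 (percentile 99.95), 15 of 22 higher, with cpn-3 at 3.24, mlc-1 at 2.32, unc-89 at 2.01 and tni-1 at -1.81. That median rested on oocyte -1 replicate 1, where the myosin light chain gene mlc-3 reached 176 CPM against 6.93 to 13 CPM in the other -1 oocytes, and without it 3 of 22 were higher, the median was -1.11 and cpn-3, mlc-1, unc-89 and tni-1 stood at 0.23, -1.01, 0.23 and -3.30. Neuron markers had a median of 0.44 (percentile 99.2), 10 of 19 higher, with snt-1 at 1.90, egl-3 at 1.86, unc-10 at -1.63 and sng-1 at -1.50. These 4 stood at or below 3.77 CPM at both positions, and a stricter filter turned the median to -0.06. The ratio of egl-3 was 2.47 without oocyte -5 replicate 3 and that of sng-1 -0.71 without oocyte -5 replicate 4. Gonadal sheath and spermatheca markers had a median of -0.17 (percentile 11.2), with inx-9 at -3.35, lim-7 at -2.54, inx-8 at -2.02, while ceh-18 was higher, at 1.42 against 0.509 CPM. The innexin gene inx-8 ranged from 10.7 to 673 CPM among the -5 oocytes. Its ratio was 0.96 and that of inx-9 -1.42 without oocyte -5 replicate 4, inx-8 and inx-9 stood at -4.33 and -4.34 without oocyte -1 replicate 1, and lim-7 at -4.16 without oocyte -1 replicate 3.

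For the lists that stood apart in any of the 3 comparisons, 19 of 60 in all, the oocyte scores of the positions lay apart in 0 of 19. The ranges over the oocytes of the positions overlapped in each of these.

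**Figure D3:**
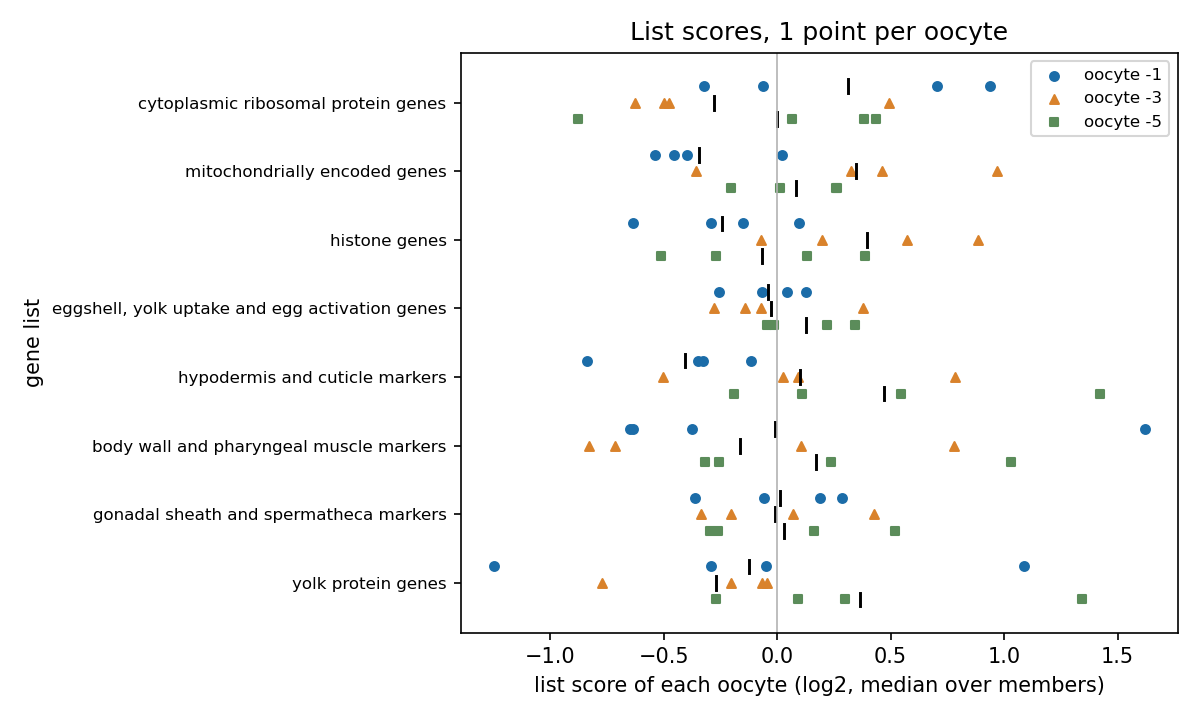
Score of each oocyte for 8 gene lists, as the median over members of log2 (CPM + 1) minus the gene's mean over the 12 oocytes, with 1 point per oocyte and a bar at the mean of each position. Oocytes of different positions overlap in each list shown, also for ribosomal protein genes, whose median log2 ratio between -1 and -5 was 0.45.

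Oocyte -1 against oocyte -3 gave the same 5 genes at the top when ranked under the same limits of level and separation, with log2 ratios of 4.90 for F57C2.4, 4.17 for ule-5, 3.64 for ZC373.2, 3.58 for ZK813.3 and 3.51 for Y62H9A.5. Both comparisons use the same -1 oocytes, so the repeat is not independent support. Oocyte -3 replicate 1 supplied most of the -3 counts of all 5, and without it their ratios were 7.45, 6.70, 5.57, 7.99 and 4.63 in that order. Lowest under these limits were the pseudogene F29G9.7 (-2.40), the RNA interference gene rde-10 (-1.68), the zinc finger gene zfp-2 (-1.59), sygl-1, a target of Notch signalling in germline stem cells (-1.54), and the fumarase gene fum-1 (-1.44). Ribosomal protein genes were higher in oocyte -1 for 75 of 80 members, with a median of 0.61 (percentile 100), led by rpl-9 (1.31), rps-6 (1.29), rla-0 (1.24) and rpl-14 (133 against 58.9 CPM). The abundant rpl-12 went the other way, at -0.62. Mitochondrially encoded genes were lower for 12 of 12, with a median of -0.73 (percentile 0.13), among them ctc-2 (-1.25), nduo-2 (-1.23), nduo-1 (-1.22) and atp-6 (-0.91). Without oocyte -3 replicate 1 the mitochondrial median was -0.45 and the ribosomal median 0.93, and without both oocytes of -3 that stood apart they were -0.76 and 0.89. Mitochondrially encoded genes took 0.837% of the summed counts at -1, 1.27% at -3 and 0.929% at -5. Histone genes were lower for 34 of 38, with a median of -0.73 (percentile 0), with hil-3 at 2.28, his-24 at -2.12 and his-41 at -1.63, and with hil-1, which had no count at -1, at -5.32 or lower by the floor of 3 counts over the group. The histone scores of the -3 oocytes that stood apart, 0.886 and 0.574, lay above those of replicates 2 and 4, -0.0695 and 0.198, and without these 2 oocytes the median was -0.33. The -3 counts of hil-1 came mostly from replicates 1 and 3, at 5.04 and 2.86 CPM, and its ratio at the floor was -4.32 without replicate 1. The ratio of hil-3 was -0.02 without oocyte -1 replicate 2, and that of his-24 -3.41 without oocyte -1 replicate 4 and -0.95 without oocyte -3 replicate 3.

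In the same comparison hypodermis and cuticle markers had a median of -0.73 (percentile 0.08), 4 of 12 higher, with noah-1 at -1.24, grd-3 at 1.23, col-119 at -1.17 and col-124 at -1.14. Single oocytes set several of these, since noah-1 stood at -2.70 without oocyte -1 replicate 1, grd-3 at 2.34 without oocyte -3 replicate 2 and col-124 at -0.25 without oocyte -3 replicate 1. The median was -0.26 without the oocytes of -3 that stood apart. Muscle markers had a median of 0.81 (percentile 100), 17 of 22 higher, with unc-89 at 2.45, mlc-3 at 2.12, clik-1 at 1.87 and mlc-1 at 1.80. Leaving out oocyte -1 replicate 1 left 4 of 22 higher and gave a median of -0.77 and ratios of 0.67, -0.81, -0.34 and -1.53 for these 4 genes. The median without the 2 oocytes of -3 that stood apart was 1.92. Yolk protein genes had a median of 0.35 (percentile 91.2), or -0.58 without oocyte -1 replicate 4, and sheath and spermatheca markers 0.11 (percentile 69.96).

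Oocyte -3 against oocyte -5, under the limits of at least 20 CPM and separated oocytes, had its highest ratios for ZK1127.3 (1.75), the RNA export factor gene nxf-2 (1.57), F32D8.5 (1.56), C06H2.7 (1.55) and sygl-1 (1.52). Of the exonic bases of F32D8.5, 31.1% overlap another gene, which leaves its count uncertain. Lowest under the same limits were the SUMO protease gene ulp-5 (-1.73), the glucose transporter gene fdgt-1 (-1.70), Y75B12B.1 (-1.46), F49D11.10 (-1.39) and the kinesin heavy chain gene unc-116 (-1.34). The ratio of fdgt-1 was -0.83 without oocyte -5 replicate 4 and that of unc-116 -1.95 without oocyte -3 replicate 4. Histone genes were higher in oocyte -3 for 31 of 38, with a median of 0.53 (percentile 100), or 0.18 without the 2 oocytes of -3 that stood apart, whose scores were the highest of that position. Without those oocytes the eggshell, ribosomal and hypodermis medians given below were -0.11, -0.48 and -1.27. The largest histone ratios were -4.47 for hil-3, 2.75 for his-69, 1.74 for his-1 and 1.43 for hil-1, genes at or below 4.21 CPM at both positions. Leaving out oocyte -3 replicate 1 gave -5.65 for hil-3, -2.16 for his-69 and 0.43 for hil-1. Eggshell, yolk uptake and egg activation genes were lower for 25 of 33, with a median of -0.22 (percentile 0.34), among them fasn-1 (-2.23), perm-2 (-1.95), perm-4 (-1.67) and perm-1 (-1.05). The ratios of fasn-1, perm-2 and perm-4 were -1.55, -0.33 and -0.25 without oocyte -5 replicate 4, and those of perm-2 and perm-4 -3.62 and -3.40 without oocyte -3 replicate 3. Oocyte -5 replicate 4 also held the highest share of sheath and spermatheca markers at -5, 0.170%, and RNA of other cells was not tested as a cause. Ribosomal protein genes were lower for 59 of 80, with a median of -0.17 (percentile 0.16), as for rla-0 (-1.04) and rps-7 (-0.78), while rpl-25.1 (0.87) and rpl-37 (0.66) were higher. Single oocytes left out gave medians from -0.499, without replicate 1 of oocyte -3, to -0.0363, without replicate 1 of oocyte -5, and rpl-37 stood at 0.06 without replicate 1 of oocyte -3. Hypodermis and cuticle markers had a median of -0.80 (percentile 0), 9 of 12 lower, with grd-3 at -3.64, far-2 at -1.38, col-140 at -1.09 and vab-10 at -1.04. That median was 0.03 without oocyte -5 replicate 4, with far-2 at -0.26 and col-140 at -0.25, and grd-3 stood at -4.75 without oocyte -3 replicate 2. Yolk protein genes were lower for 6 of 6, with a median of -0.45 (percentile 3.70). That count was 3 of 6 without oocyte -5 replicate 3, where the median was -0.18, vit-3 stood at 0.23 and vit-6 at 0.05, and vit-4 stood at 0.63 without oocyte -5 replicate 2. Sheath and spermatheca markers had a median of -0.32 (percentile 5).

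Ratios were also set beside those of the authors' deposited tables. Both come from the same libraries, so their closeness compares ways of computing and gives no independent support to any ratio. Across the 7248, 7530 and 7243 genes in both, the Spearman correlation of log2 ratios was 0.967 for -1 against -5, 0.981 for -1 against -3 and 0.988 for -3 against -5, and genes are not independent replicates. The sign was the same for 92.8%, 94.7% and 95.6% of these genes. In the authors' deposited tables the Wald score had the opposite sign to the log2 fold change in 7286 of 7286, 7585 of 7585 and 7277 of 7277 genes, so their 2 columns give opposite directions. The log2 fold changes were used as deposited, and their direction is the one that matches the counts. For ZC373.2 the authors' deposited table gave a log2 fold change of 4.49 between -1 and -5, for ule-5 4.20 and for rme-2 -1.19.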

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

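The tests in this part were chosen after the results were seen. In 72 groups of 4 oocytes, 5 held an oocyte far from the other 3 by the ratio of its gap to the range, and chance gives about 1 in 20. Hypodermis and cuticle markers took 0.178% of the counts of oocyte -5 replicate 4, against 0.0351% to 0.0469% in the other -5 oocytes. Heat shock and stress genes took 1.38% in oocyte -1 replicate 1, against 2.1% to 2.2%. Nuclear oxidative phosphorylation genes took 1.44% in oocyte -3 replicate 1, against 1.23% to 1.25%. Intestine markers took 0.00420% in oocyte -3 replicate 4, against 0.00251% to 0.00270%. Sperm genes took 0.0110% in oocyte -5 replicate 3, against 0.00477% to 0.00576%.

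Oocyte -3 replicates 1 and 3 lay apart from the other 10 libraries on the first 2 principal components. Lower depth is argued against, since the lower of their totals was 16140400 counts, and 16.14 against a median of 12.63 for the other 10 in units of 1e6 counts. Fewer transcripts captured remains a candidate explanation, since after thinning the higher of their gene numbers was 8453 and the lowest of the others 9040. A higher share of counts in a few genes stays open. The share of the 10 most abundant genes was 15.2% in replicate 3, within the range of the others, and 21.98% in replicate 1, above their highest of 16.6%. It was thus above that range in replicate 1 only, and these genes took most of the counts in neither oocyte. No biological explanation was tested, and the state of these oocytes before lysis is not known here.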

How the results depend on the processing

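Leaving out single oocytes, RLE factors, library totals and the stricter filter were among the alternatives planned before the data were examined, and all others were chosen after seeing the data. Of 313 values of the 19 list medians under alternatives, 301 kept their sign and moved by less than 1 SD between oocytes, 7 moved further and 5 changed sign. That SD was larger than several of the medians, as for ribosomal protein genes between -1 and -5 (0.61 against 0.45) and muscle markers (1.09 against 0.41). A median could thus lose most of its size and still count among the 301, so the tally does not show that the medians are stable. Of 560 values of the 36 gene ratios named by size, 11 moved by over 1 SD. Those genes were chosen with the oocytes of 2 positions fully apart, so leaving out oocytes could not turn their sign. Of the 186 other named gene ratios, 50 changed sign without 1 oocyte. Without single oocytes the muscle median ranged from -1.11 to 0.997 for -1 against -5 and from -0.766 to 1.29 for -1 against -3, with the lowest value in each without oocyte -1 replicate 1. Without the 2 oocytes of -3 that stood apart the latter was 1.92. The neuron median for -1 against -5 ranged from 0.0872 to 0.623 without single oocytes, and was 0.204 with no filter and -0.0615 with the stricter filter, which measures fewer genes. The median of the RNA-binding regulators ranged from -0.0247 to 0.0857, and that of hypodermis and cuticle markers for -3 against -5 from -1.21 to 0.0343. The cell cycle and spindle median was 0.149 with library totals. The difference in genes detected between -1 and -5 was 57.0, and -44.2 when a gene needed at least 5 counts. The cause was not tested for any of these. With library totals the median of all genes shifted to 0.21 for -1 against -3 and to -0.13 for -3 against -5, so ratios are relative to the scaling used. No paired analysis was possible because the values reported come from no test that a block could enter. The mean of log2 ratios within replicate numbers is the difference of the mean log2 levels whichever numbers are matched, so matching would change an error only, and none is reported. Alternatives planned for tests were not run on the values reported. Depth limits genes of low level, such as hil-1 and the neuron markers named above.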

Other observations

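Other lists of oocyte genes had medians within the percentiles 2.5 and 97.5 of the random lists in each comparison. P granule and small RNA pathway genes had median log2 ratios of 0.10 for -1 against -5, 0.19 for -1 against -3 and -0.004 for -3 against -5, at percentiles 96.8, 96.8 and 55.5 of the random lists. The P granule gene pgl-1 stood at 657, 445 and 371 CPM in oocytes -1, -3 and -5. Meiotic chromosome axis and recombination genes had medians of 0.10 in each comparison (percentiles 96.5, 74.4 and 94.0). In that list the scores of the -1 oocytes, 0.0195 to 0.166, lay above those of the -5 oocytes, -0.0676 to 0.00263, a separation that chance gives to 2.86% of such comparisons. It was the only separation of scores among the 60 comparisons of lists, no more than that rate would give by chance. The cohesin gene rec-8 stood at 65.8, 60.6 and 51.2 CPM and the synaptonemal complex gene syp-1 at 58.0, 43.1 and 56.4 CPM. The Notch receptor gene glp-1 stood at 127.9, 112.9 and 103.5 CPM, and mei-1, a subunit of katanin, at 284, 280 and 307 CPM. Nuclear oxidative phosphorylation genes had medians of 0.06, -0.01 and 0.13, translation factor genes 0.03, 0.11 and -0.09, oocyte cytoskeleton genes -0.03, 0.06 and -0.02, and heat shock and stress genes -0.06, 0.08 and -0.21. The constitutive chaperone gene hsp-1 stood at 557, 613 and 900 CPM and the inducible hsp-70 at 2.53, 2.81 and 1.49 CPM. The log2 ratio of hsp-70 was 0.44 in place of -0.15 for -1 against -3 without oocyte -3 replicate 3. Without oocyte -5 replicate 1 it was 1.55 in place of 0.76 for -1 against -5, and 1.70 in place of 0.92 for -3 against -5. Of the sperm genes only 4 of 59 were measured, with medians of -0.44, -0.27 and 0.02. Coelomocyte markers took 0.0142%, 0.00982% and 0.0115% of the counts at -1, -3 and -5.

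Some transcripts varied more among oocytes of a position than between positions, and these examples were chosen after their values were seen. The barrier gene perm-2 ranged from 65.3 to 1011 CPM among the -5 oocytes and perm-4 from 85.2 to 1020 CPM, both highest in replicate 4. The sheath innexin gene inx-8 was highest there too, at 673 CPM. In oocyte -1 replicate 1 the muscle genes cpn-3, mlc-3, clik-1 and unc-89 reached 201, 176, 111 and 16.8 CPM.

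The tests named in the rest of this part were chosen after the results were seen. Ribosomal protein genes were higher and mitochondrially encoded genes lower in oocyte -1 than in oocyte -3. Gene length bias is argued against as the whole cause. After a lowess line over exonic length was taken out, the median log2 ratio was 0.87 for the ribosomal genes and -0.56 for the mitochondrial genes. Both lay beyond the median absolute deviations among members, scaled to match an SD, of 0.278 and 0.251. Those deviations describe the spread of the genes and not the error of the median. The 2 oocytes of -3 that stood apart are argued against as the whole cause. With all oocytes the ribosomal median was 0.61 and the mitochondrial median -0.73. Without both oocytes they were 0.89 and -0.76, beyond the larger SD between oocytes of the list score (0.603 and 0.547). A part played by either oocyte alone stays open, because the 2 oocytes pulled in opposite directions. Without replicate 3 alone the ribosomal median was 0.48, and without replicate 1 alone the mitochondrial median was -0.45, within those SDs. A biological difference between the positions may be behind the pattern, as a hypothesis that stays untested, and the oocyte scores of the positions overlapped.

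The 5 genes F57C2.4, ule-5, ZC373.2, ZK813.3 and Y62H9A.5 were higher in every -1 oocyte than in the oocytes of both other positions. Reads of an annotated overlapping gene are argued against, since 0% of their exonic bases overlap an exon of another gene, but this set was settled on after another had been looked at, the genes with a mean of at least 20 CPM over the 12 oocytes that lay highest in all -1 oocytes, which holds 2 of the 5 and in which the overlap reached 20.5% and left that explanation open. RNA of gonadal sheath or spermatheca cells, which lie next to the oocyte, may be the source, as a hypothesis, although the abundant sheath innexin gene inx-8 stood at 3.92 and 4.44 CPM in -1 replicates 2 and 4, where each of the 5 reached at least 40.2 CPM, and at 673 CPM in -5 replicate 4, where each was at most 0.46 CPM. Of 25 markers of these cells 21 were measured, with a median log2 ratio of -0.17 between -1 and -5, an SD between oocytes of 0.387 and members on both sides of 0. The spermatheca genes fkh-6 and sth-1 were among those not measured. Members such as fln-1, at 138, 142 and 191 CPM in oocytes -1, -3 and -5, would hide a small share. RNA of these cells and transcription in the oocyte therefore cannot be told apart. Explanations other than those named here were not tested.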
